A study of Drosophila melanogaster with 4 samples.

How the data were processed

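Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos with an antibody against Scute. Per the labels, the series held 4 libraries, 2 of ChIP DNA and 2 of input DNA, all from the y; cn bw sp strain. Input DNA is chromatin taken without the antibody step and serves as the background of the peak caller. The antibody was a crude polyclonal serum raised in guinea pig. The labels give the stage as 0 to 8 h embryos, while the collection protocol attached to all 4 samples is worded for 8 to 16 h, so the window was taken from the stage label.

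The deposited file was a single peak list in GFF3 format with a start, an end and a score for each peak. BWA, MACS2, and CASAVA versions 1.7.0.2 and 1.7.0.3 are named in the submitters' processing notes, with the genome build BDGP5. Per the file headers, the coordinates are those of FlyBase release 5 and the caller is given as MACS. How the 2 ChIP and 2 input libraries were combined, the calling threshold, duplicate handling and the treatment of reads that map to many places are not given in the sources used here. The deposited score of each peak was read as a −log10 p-value made by the authors' peak caller, a reading that rests on the values themselves. Of the 1276 scores, 44.4% lay within 0.006 of −log10 of a Poisson tail probability at a whole-number height and a single mean of 55.7. Shifting each score at random by up to 0.25 brought that share to 3.08% (mean of 200 draws), and in a scan of means from 2 to 200 in steps of 0.001, the highest share over 0.5 away from the best mean was 13.3%. A score at this mean is called a score at the common background below. MACS is known to test each position against the largest of a genome-wide mean and local means from the control library, so the common background was taken to be the genome-wide mean.

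No values per library were used, since the list holds 1 value per peak. Replicate spread could therefore not be measured, depth per sample is unknown, and no interval here covers differences between embryo collections. Intervals on shares are exact Clopper-Pearson intervals at 95% over peaks, which are not independent replicates. The score was used only within the list, to rank and describe peaks, to compare groups of peaks and to derive Poisson heights.

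Tests were fixed before the data were examined, except where stated. Peak numbers on arms 2L, 2R, 3L, 3R, 4 and X were compared with arm length by a chi-square statistic with 100000 random placements, and X was compared with the 4 large autosome arms by an exact two-sided binomial test. The length of an arm was the span from its first to its last peak, because no sequence of the build was used. Clustering was measured as the number of peaks whose midpoint lay within 5 kb of another, against 1000 random placements of the same widths on the same arm without overlap. The peaks named in the text are the 20 with the highest scores, a rule fixed beforehand. Runs of at least 5 peaks separated by at most 10 kb, the tandem array on 2L, the distal 25 kb of arms, the comparisons of X with autosome scores and widths, of the 4 large arms with one another, and of unplaced with placed peaks, the joining of peaks within 10 kb and the shares and densities at the common background were chosen after the values were seen. Differences in medians and shares were tested two-sided, by permutation with 100000 resamples and by Fisher's exact test. The tandem array is the stretch of 2L covered by the runs that hold at least 2 peaks of 2500 bp or more.

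On simulated data with the real arms and widths, the clustering test gave p at or under 0.05 in 10 of 200 placements with no clustering and in 200 of 200 with 30% of 953 peaks placed beside another. The number of simulations had been raised from 50 to 200 because 6 of the first 50 without clustering gave such a p. The arm test gave it in 1 of 50 even placements, and in 49 of 50 simulations of an X density ratio of 0.4 the interval held that ratio. Of 1276 simulated scores, about 40% were made at a mean of 42.35 and the rest at higher means. In this 1 simulation the estimated mean was 42.35, and the share found at it was 42.2%.

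Alternatives were the 638 or 319 highest-scoring peaks, peaks within 500 bp merged, neighbour distances of 2 and 20 kb, and others added later. Peak position relative to genes, E-box and other motif content, the relation of motif to score, and 21 gene lists had been planned. They were not run, because the gene table at hand belongs to release 6 and carries no sequence, and coordinates were not moved between releases. For the same reason no peak is assigned to a gene. That table was used only for gene names and their neighbours. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.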

Results

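Scute is a basic helix-loop-helix transcription factor of the achaete-scute complex, known for promoting neural precursor fate and for its part in counting X chromosomes during sex determination. The experiment asked where Scute is bound in the genome of whole embryos, by comparing ChIP DNA with input DNA. The groups were 2 ChIP and 2 input libraries of 0 to 8 h embryos of the y; cn bw sp strain. The available values are a single list of 1276 peaks with positions in FlyBase release 5, so every value below describes that list, none has a replicate error, and the depth of each library is unknown.

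The 1276 peaks covered 635 kb. Their median width was 369.5 bp, with an interquartile range of 261 to 569 bp, and the widest spanned 4246 bp. The score, −log10 of a p-value, had a median of 13.3 and ran from 6.07 to 109.88. The 6 placed arms held 953 peaks, which is 74.7% of the list. U and Uextra, the release 5 collections of sequence not placed on an arm, held 34 and 286 peaks. The remaining 3 peaks lay on 2LHet and 2RHet, which hold heterochromatic sequence.

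The highest scores were spread over several autosomal sites. The highest score of the list, 109.88, belonged to a peak of 826 bp on 3R from 8889516 to 8890341. The next was on 2R from 15993770 to 15994302, with a score of 94.74 and a width of 533 bp. The 3R peak from 21856170 to 21857141 scored 91.47 over 972 bp and had 6 other peaks within 10 kb. On 3L a peak of 690 bp from 7905369 to 7906058 scored 84.73 and stood alone, with the nearest other peak 66.6 kb away. The 2R peak from 6310853 to 6311633 scored 63.13 and had 4 other peaks within 10 kb. On 2L, the peak from 4811257 to 4811922 scored 55.44, and the isolated peak from 3152658 to 3153170 scored 54.74 with its nearest neighbour 264 kb away.

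These 7 peaks were the only ones among the 20 highest scores that lay on an arm outside a tandem array on 2L. Another 7 of the 20 were in that array and 6 were on U or Uextra. Among the 6 unplaced peaks, the score was 55.44 on Uextra from 5902491 to 5903276 and 54.87 on U from 2175345 to 2177469. The other 4 were Uextra peaks from 13640863 to 13641450 with a score of 54.29, from 14774303 to 14774885 and from 17757222 to 17757764 with 53.72 each, and from 3901916 to 3902745 with 52.58. The strongest peak on X, named here after its value was seen, lay from 19472533 to 19473499 and scored 43.24.

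**Figure D1:**
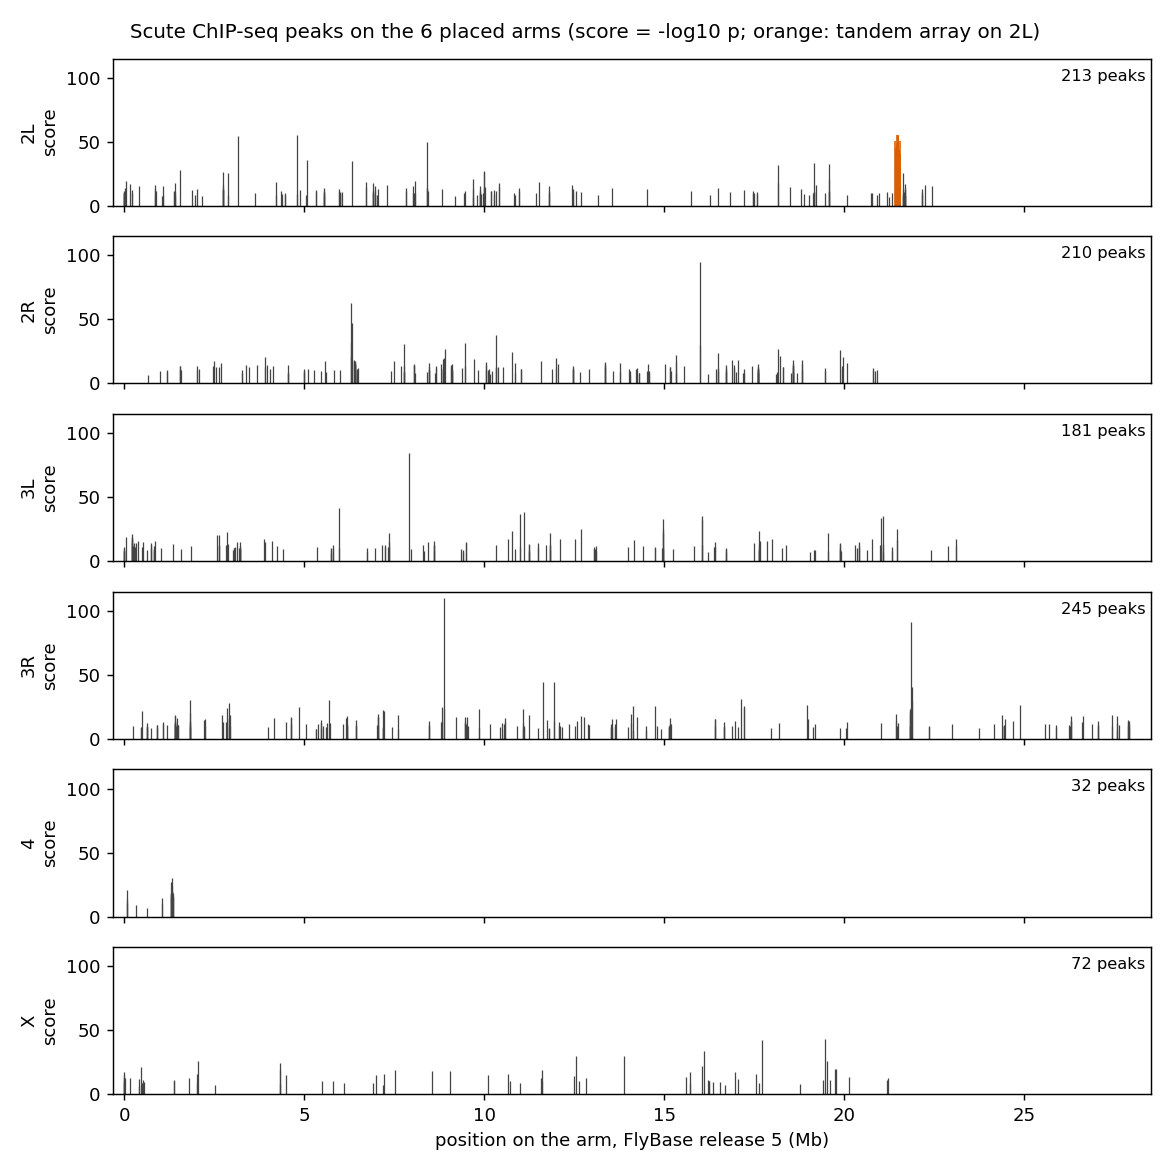
Each vertical line is a peak on arm 2L, 2R, 3L, 3R, 4 or X, placed at its midpoint in Mb of FlyBase release 5, with its height giving the score (−log10 p, linear axis). Orange lines are the 31 peaks of the tandem array on 2L, the 4 scores above 80 lie on 2R, 3L and 3R, and X carries 72 peaks against 181 to 245 on each large autosome arm.

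Peaks were unevenly shared among the chromosomes, and X was the sparse one. Arm 2L carried 213 peaks, 2R 210, 3L 181, 3R 245, X 72 and the small chromosome 4 carried 32. Per Mb of the span between first and last peak, this was 9.50 on 2L, 10.4 on 2R, 7.84 on 3L, 8.86 on 3R, 3.39 on X and 25 on chromosome 4. The density on X was 0.373 times that of the 4 large autosome arms (95% interval 0.289 to 0.475; exact two-sided binomial p = 4.3e-20). Over all 6 arms the Monte Carlo chi-square p was 1e-05, the smallest that 100000 placements can give.

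Both tests treat peaks as independent, although many lay side by side. With all peaks within 10 kb counted as 1 region, X held 60 regions against 102 to 145 on each large autosome arm. The density ratio was then 0.559 (95% interval 0.420 to 0.733; exact binomial p = 7.3e-06). For the peaks found on X, no difference in score or width from those of the large autosomes outside the 2L array was detectable. Their median score was 12.6 against 11.6 (X minus autosome 0.97, 95% bootstrap interval -0.64 to 2.81; permutation p = 0.1 over 72 and 818 peaks). Their median width was 325 against 318 bp (X minus autosome 7 bp, 95% bootstrap interval -40 to 61; permutation p = 0.68). These intervals are over peaks, not over replicates.

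The 4 large autosome arms resembled one another more closely. Outside the array, peaks per Mb were 8.11 on 2L, 10.4 on 2R, 7.84 on 3L and 8.86 on 3R (Monte Carlo chi-square p = 0.023). With the same peaks joined into regions, the 4 arms held 100, 120, 105 and 145. This did not pass the threshold of 0.05 (Monte Carlo chi-square p = 0.11). On chromosome 4, 22 of the 32 peaks lay in its last 36.3 kb, from 1315363 to 1351689, with a median score of 16.0. The other 10 peaks gave 8.04 per Mb, against 7.84 to 10.4 on the large arms outside the array. This is not a like comparison. Leaving out the run with the most peaks lowers a density by construction, and the large arms kept their other runs.

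Scute peaks came in groups. Of the 953 peaks on the 6 arms, 554 (58.1%) had another peak midpoint within 5 kb, against 75.4 ± 11.6 (SD, 1000 random placements), a 7.35-fold excess (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Without the 2L array the count was 529 of 922, a 7.34-fold excess. With the peaks at the ends of 2L, 3L, X and chromosome 4 also left out it was 489 of 881, a 7.58-fold excess. The excess was 16.5-fold within 2 kb and 2.33-fold within 20 kb. Some neighbours may be parts of a single enriched stretch that the caller split. Merging peaks within 500 bp took the 953 arm peaks to 790, and the clustering test was not repeated on the merged list. These excesses and the groups below therefore count called peaks, not separate sites.

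Joining peaks separated by at most 10 kb gave 538 groups on the arms, of which 351 were single peaks, 160 held 2 to 4 peaks and 27 held at least 5. Outside the array and the arm ends, 21 groups held at least 5 peaks, while 1000 random placements gave 0.033 such groups on average and never more than 2. The longest of them held 14 peaks over 43778 bp on 3R, from 21824851 to 21868628, and contained the peak scoring 91.47. On 2R, 9 peaks lay between 17590154 and 17610371, with a median score of 11.2, and 8 lay between 6410455 and 6422540, with a median of 15.0. A further 6 peaks lay between 6305427 and 6325741 on 2R, with a median score of 26.1, and included the peak scoring 63.13. On 3L, 7 peaks between 224217 and 240610 had a median score of 17.4, and 5 peaks between 14962180 and 14971128 had a median of 21.6. On 3R, 7 peaks lay between 1421196 and 1426689, with a median score of 12.8. The groups named are examples, chosen after their values were seen.

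A stretch of 2L differed from the rest of the genome in peak shape. From 21417033 to 21543562, 31 peaks covered 89.6 kb of 126.5 kb (70.8%), with a median score of 40.6. Of these, 22 were at least 2500 bp wide, with a median of 3855 bp and scores of 37.5 to 54.9. Only 1 other peak of the list reached that width, at 2915 bp, also on 2L. The 22 wide peaks gave 21 steps from start to start, of which 19 were under 8 kb. These 19 had a median of 5031 bp (SD 92.3, range 4787 to 5114), and 18 of them were within 200 bp of it. The other 2 steps were 10111 bp, where narrower peaks filled the space, and 14079 bp, which held the longest stretch without a peak, 10327 bp. Over the 19 shorter steps the gap between wide peaks had a median of 1178 bp. All 7 array peaks among the 20 highest scores were such wide peaks. They ran from 21461270 to 21465082 and from 21486550 to 21490441 with scores of 54.87, from 21491640 to 21495496 with 54.29, from 21481477 to 21485292 with 53.72, from 21476396 to 21479423 with 51.45, and from 21417033 to 21420713 and from 21536420 to 21539430 with 50.32 each.

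**Figure D2:**
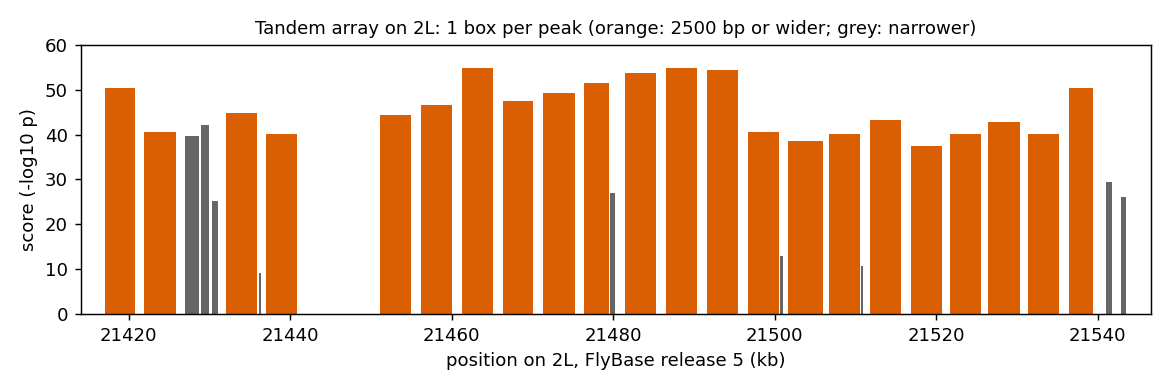
Each box is a peak of the tandem array on 2L, drawn from its start to its end (kb, FlyBase release 5) and up to its score (−log10 p); orange boxes are at least 2500 bp wide and grey boxes are narrower. Starts of neighbouring orange boxes are a median of 5031 bp apart over 19 steps, and the row is interrupted at steps of 10111 and 14079 bp.

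Peaks were also dense at the outer ends of 2L, 3L and X, the arms that are numbered from their distal end. The outer ends of 2R and 3R were not tested, because no sequence of the build was used to place them. The first 25 kb of these 3 arms held 8, 5 and 6 peaks, 19 in all. From the density of the arms outside the array, 0.484 were expected. The excess was 39.3-fold (one-sided Monte Carlo binomial p = 1e-05, the smallest that 100000 draws can give). Most were weak: their median scores were 10.3 on 2L, 8.59 on 3L and 12.9 on X, and the highest was 17.6, on X. Among the 638 highest-scoring peaks, 3 lay there, against 0.163 expected (one-sided Monte Carlo binomial p = 0.0006). These draws place peaks independently, and on each arm the peaks formed a single region. Counted as regions, 3 lay there against 0.296 expected, a 10.1-fold excess (one-sided Monte Carlo binomial p = 0.0034). The window was chosen because these peaks had been seen.

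**Figure D3:**
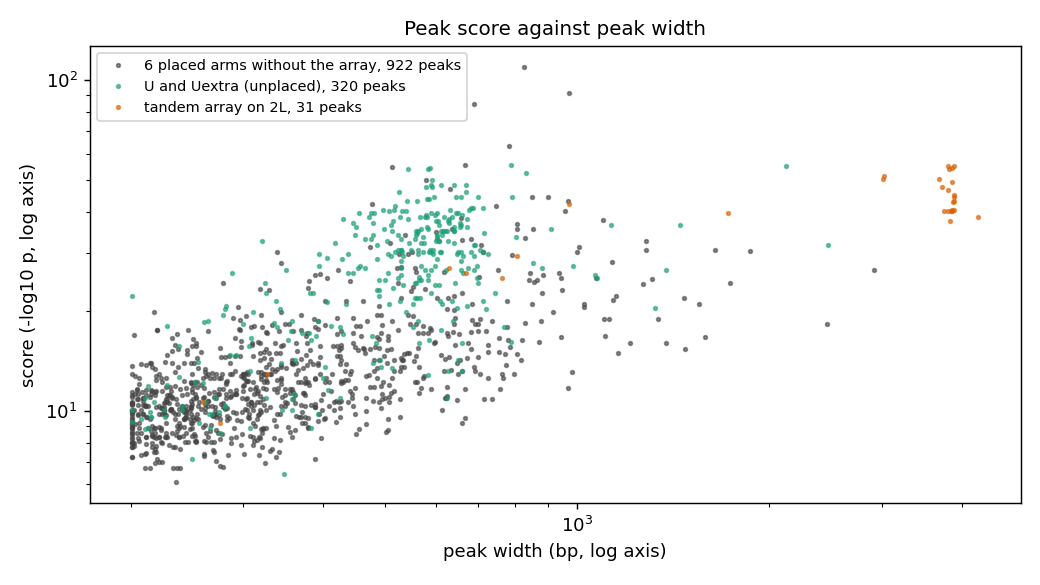
Each point is a peak, with its width (bp, log axis) and its score (−log10 p, log axis). Of the 31 peaks of the array on 2L, 22 sit at the largest widths, near 3855 bp, and the 320 peaks of U and Uextra have a median score of 27.5 against 11.7 for the 922 peaks of the arms outside the array.

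Groups of peaks differed in how often their scores lay at the common background. On the large autosome arms outside the array, 228 of 818 peaks (27.9%, 95% exact interval 24.8 to 31.1) had a score at the common background, and on chromosome 4 it was 8 of 32 (25%, 11.5 to 43.4). On X it was 55 of 72 (76.4%, 64.9 to 85.6), which is 48.5 percentage points more than on those autosome arms (Fisher's exact two-sided p = 5.4e-16). Peaks at the common background showed no detectable difference in density between X and the large autosome arms with the array, at 2.59 and 2.74 per Mb (ratio 0.945, 95% interval 0.693 to 1.27; exact two-sided binomial p = 0.77). The other peaks numbered 17 on X and 593 on those arms, or 0.801 and 6.35 per Mb (ratio 0.126, 0.0730 to 0.204; exact binomial p = 7.6e-33). In the 2L array the share was 28 of 31 (90.3%, 74.2 to 98.0), 62.4 percentage points more than in the other large-autosome peaks (Fisher's exact p = 1.6e-12). The tolerance of 0.006 missed some recurring scores that lay close to a whole-number height, such as 10.03 in 18 peaks and 40.61 in 6. With a tolerance of 0.02 the share was 91.7% on X (66 of 72), 37.8% on the large autosome arms outside the array and 100% in the array (31 of 31), with 10.2% by chance against 3.08% at 0.006. The X peaks off the common background then fell to 6 against 509, a density ratio of 0.0519 (0.0189 to 0.114; exact binomial p = 8.7e-37), and the ratio at it was 0.854 (0.646 to 1.11; exact binomial p = 0.25). These comparisons were added after the scores were examined. Their p-values treat peaks as independent, although the 31 array peaks lie side by side on 2L.

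**Figure D4:**
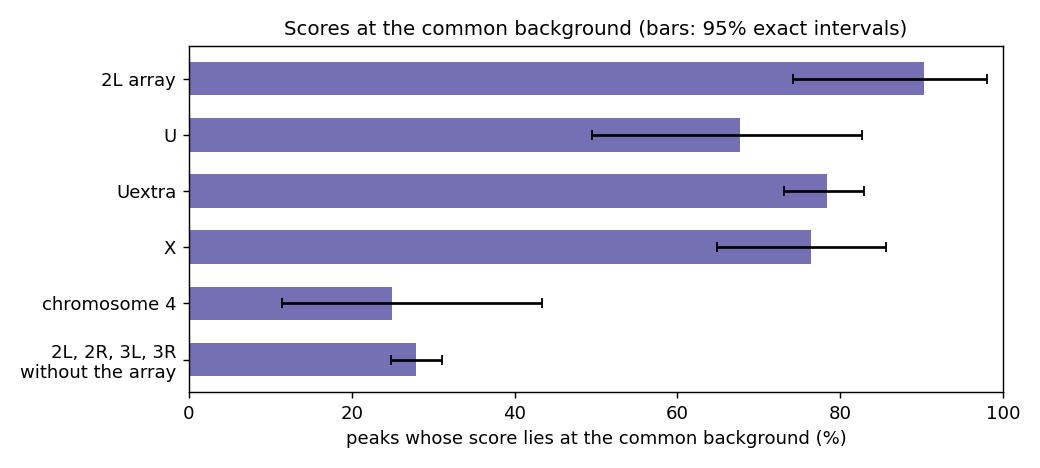
Bars give the percentage of peaks whose score lies at the common background, for 6 groups of peaks, and error bars are 95% exact intervals over peaks. The 2L array (90.3%), Uextra (78.3%), X (76.4%) and U (67.6%) lie above chromosome 4 (25%) and the large autosome arms outside the array (27.9%).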

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

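The tests in this part were chosen after the peak list was examined. They treat peaks as independent, which peaks on repeated sequence may not be. The 320 peaks on U and Uextra and the 3 on 2LHet and 2RHet lie outside the comparisons of arms, and no control peak list was used beside them, so they stand here as signal in sequence that was not otherwise analysed. The unplaced peaks were strong. Their median score was 27.5 against 11.9 for the 953 peaks of the placed arms (unplaced minus placed 15.6; permutation p = 1e-05, the smallest that 100000 resamples can give). Of the 319 highest-scoring peaks, 208 were unplaced, 28 were in the 2L array and 110 were on arms with the array included. That is 65.0% of unplaced peaks (95% exact interval 59.5 to 70.2) against 11.5% of placed ones (9.58 to 13.7; Fisher's exact p = 1.4e-74). Most of the difference came from Uextra, whose 286 peaks had a median of 29.2, while the 34 peaks on U had a median of 17.1 (U minus placed 5.18; permutation p = 6e-05). On U, 19 peaks with a median score of 23.2 lay between 2150923 and 2187413. The 3 peaks on 2LHet and 2RHet had a median score of 10.4 and a highest score of 23.7.

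A raised input level over unplaced, repeated sequence would have moved scores off the genome-wide mean, since MACS uses the largest of its background means. Instead 77.2% of the unplaced peaks (247 of 320) scored at the common background, 49.3 percentage points more than large-autosome peaks outside the array (Fisher's exact p = 9.6e-53). Under that rule, the local control level was not above the genome-wide mean at these 247 peaks. At an unchanged ChIP height, a raised level would lower a score. Where ChIP and input heights rise together, the score need not fall, and this was not tested. Stretches where a raised level removed a peak are not in the list, so the share cannot show how common a raised level was. Reads placed at random among repeated copies, assembly artefacts of these scaffolds, and Scute bound to repeated sequence all remain open and were not tested. The design names no group that bears on a biological explanation.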

How the results depend on the processing

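The alternatives for arm ends, unplaced peaks and the common background (shares and densities), the 10 kb regions, the length from base 1 and the lists without the 2L array were chosen after the data were seen. No paired analysis was possible because the series has 1 peak list with no value per library, so replicates could neither be paired nor left out. Of 28 alternatives, 25 were counted as unchanged. For tests this meant the same direction and side of the threshold as the value they recompute. The number of peaks has neither and was judged by its closeness to 1276, which the list with peaks within 500 bp merged passed. The X to autosome density ratio at the common background turned from 0.945 to 1.06 without the 2L array, and neither value passed the threshold; leaving out array peaks lowers the autosome count by construction. The number of peaks followed the threshold by construction, from 1276 to 638 for scores above the median and 319 for the highest 25%, and was 1093 with peaks within 500 bp merged. The X to autosome density ratio lay between 0.377 and 0.559 over its alternatives, above the 0.373 of the full list in each. It was highest with peaks within 10 kb merged into regions. The clustering excess ranged from 2.33-fold within 20 kb to 16.5-fold within 2 kb and was 12.1-fold among the 638 highest-scoring peaks. It was not recomputed with peaks within 500 bp merged. The excess at arm ends was 72.4-fold in 10 kb, 20.7-fold in 50 kb, 18.4-fold among the 638 highest-scoring peaks and 10.1-fold with peaks within 10 kb merged into regions. The X minus autosome share at the common background was 46.2 percentage points with all peaks and 48.5 to 51.6 under its alternatives. The density ratio off it fell from 0.126 to 0.0519 with a tolerance of 0.02. Arm length in bases other than N was not run, since no sequence of the build was used, and the planned gene, motif and gene-list alternatives were not run either. Read depth and replicate spread, which set how reliable the weakest peaks are, are unknown.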

Other observations

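In this part, the histone gene count and the test of lowered heights were written down before their results were seen, and the shares and densities at the common background were chosen after. Beyond the 20 highest scores, other high-scoring peaks on the arms outside the 2L array included a 2L peak from 8416534 to 8417112 with a score of 50.06. A second peak of the 2R group, from 6315791 to 6316422, scored 46.83. On 3R, 2 peaks from 11925142 to 11925991 and from 11619486 to 11620385 scored 44.31 and 44.22. On X, peaks from 17720984 to 17721460 and from 16111244 to 16111781 scored 42.18 and 34.08 and had no other peak within 10 kb. The group of 14 peaks on 3R held a second strong peak, from 21865413 to 21866367 with a score of 40.1. These peaks were chosen after their values were seen.

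The score ladder also gives heights. If scores at the common background are Poisson probabilities at a mean of 55.7, the 567 peaks there had heights of 96 to 266, with a median of 135, that is 1.72 to 4.77 times that mean. A peak tested against a higher local mean has a lower ratio for the same score. No peak of the list, the highest included, would therefore exceed 5.24 times the mean it was tested against, and the median peak would not exceed 2.14 times. These are not bounds over a peak's own input. At the common background the local control may lie below the genome-wide mean, and the ratio to it would then be higher. Heights could be off by 1 under another convention for the tail, and scaling of libraries by the caller was not tested. With a tolerance of 0.02 in place of 0.006, the difference in this share between X and the large autosomes was 51.6 percentage points.

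The low number of peaks on X is a pattern to follow up. A candidate explanation is dose: in a pool of male and female embryos X is present in fewer copies than an autosome, so its local control would lie below the genome-wide mean. A lower X copy number in the embryo pool predicts more X scores at the common background, and 76.4% of X peaks had one against 30.2% on the large autosome arms. The deficit of X lay in the other peaks (17 against 593, density ratio 0.126, and 0.0519 with a tolerance of 0.02), while peaks at the common background had a ratio of 0.945 (0.693 to 1.27; 0.854 with that tolerance), so the share largely restates the deficit and leaves dose and fewer sites of that kind on X both open. Lowering the heights of the 256 autosomal peaks at the common background to 0.75 left 28.9% (interval 23.4 to 34.9) at or above the lowest X score. With all peaks counted, the X density was 37.3% of that of the large autosome arms (28.9 to 47.5). The kept share lay below it, with overlapping intervals. This cannot show whether a lowering of that size gives the deficit seen, because the kept share covers only autosomal peaks at the common background. In that class X had no detectable deficit, and the 593 other autosomal peaks were left out of the calculation. Nor does the calculation separate dose from fewer sites. A lower dose would itself move X peaks onto that background, so the ratio of 0.945 may not compare peaks of the same kind. No biological explanation was tested.

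The tandem peaks on 2L may lie over a repeated gene unit. By the MACS rule above, the local control level was not above the genome-wide mean at the 90.3% of array peaks at the common background. This covers called peaks only. A raised level would lower scores at an unchanged ChIP height, but need not where ChIP and input heights rise together, which was not tested. For tandem histone gene units, the release 6 gene table lists 111 replication-dependent histone genes on 2L, in 87 adjacent pairs, with 20 copies of the gene with the fewest, His2A, and 23 of His1, His2B and His3. Fewer than 20, or another family on 2L with 20 or more tandem copies, would have argued against this explanation. The longest other family, sncRNA, reached 18. However, no peak enters these counts and positions were not compared between releases, so what the array lies over stays open. Antibody binding that does not depend on Scute and the placement of reads among repeated copies also remain open, and no biological explanation was tested.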
